A study of Mus musculus with 35 samples.

How the data were processed

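Gene expression was measured in whole lung of male CD-1 mice, an outbred stock, that breathed clean air or air with styrene at 1 of 6 concentrations from 1 to 120 ppm. Each of the 7 groups held 5 mice, and each mouse gave 1 array, 35 in all. Per the labels, RNA was extracted with Trizol and RNeasy columns and labelled with an Affymetrix kit that primes from the poly(A) tail. The values deposited by the authors are log2 probe set summaries made with RMA, which corrects background, normalises between arrays and summarises probes. The labels also name Partek, with no version or role for either tool. The quartiles of the deposited values differed between arrays, so the arrays did not share an identical distribution. Array data have no read depth, and the number of arrays limits the precision.

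The table held 45037 probe sets. Gene symbols came from the platform annotation and were checked by Entrez identifier against the reference gene table, which matched 28689 probe sets and updated 0 symbols. A gene was represented by its brightest probe set with exactly 1 symbol, by the mean over all arrays. This gave 17097 genes from 28898 probe sets, and 7180 of these genes had more than 1 probe set. The 551 probe sets with several symbols and the 15588 with no gene in the annotation were left out of the gene tests. No filter on dim genes was applied, and no control probe sets were in the table, so RNA quality could not be read from them.

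A linear model with a mean for each of the 7 groups was fitted to every gene with limma 3.58.1 in R 4.3.3, with eBayes moderation of the variance. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes within a comparison. Each concentration was compared with air, and 120 ppm with 40 ppm. A trend over log2(ppm + 1) and a moderated F test of any difference among the groups used all mice. Errors of fold changes are standard errors from this fit, and all tests are two-sided. The comparisons with air share the same 5 controls, so their results are not independent of each other. The p-values measure the spread between mice of a group and no other source of error. The comparison of 120 ppm with the 10, 20 and 40 ppm groups together, the trend over 10 to 120 ppm alone and the comparison of 5 with 10 ppm were added after the data had been seen.

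Gene sets were 39 lists of pathway genes and cell type markers fixed in advance, with 575 of 653 members measured. They were tested with limma's camera at its preset correlation of 0.01, which compares a list with all other genes, and adjusted over the lists within a comparison. Camera with a correlation estimated from the residuals, and fry, which asks whether the genes of a list move one way on balance, were run beside it. Within a list, genes were also adjusted over the list alone. Lists were called between concentrations as additions made after the data had been seen.

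The genes named were set by a rule. For 120 and 40 ppm against air they are the 10 largest rises and the 10 largest falls among called genes whose 5 exposed mice all lie on the same side of the control mean, and up to 4 called members of each list by smallest adjusted p. For the other comparisons they are the 5 largest in each direction, and for the trend the 5 with the smallest adjusted p in each direction. Cyp2f2, Cyp2e1, Cyp2b10, Scgb1a1, Mki67, Nqo1, Gsta4, Cdkn1a and Dbp could be named whatever they did. List members named for 120 ppm against lower concentrations were chosen after their values had been seen.

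Arrays were compared by their interquartile range and their score on the first principal component with exact permutation tests over all 252 arrangements of 5 against 5 mice, adjusted over 16 tests. The largest single axis of the spread between mice of the same group, which carried 18.8% of it, was scored on every array. It was used as a covariate, called the array axis here. On this axis and on the interquartile range, arrays in air did not overlap those from 5 ppm up. In those comparisons a call lost, a call gained or a sign turned with either covariate does not separate an array-wide difference from an effect of exposure. Changes fitted there with either covariate are extrapolated, because the groups compared shared no range of it. A clock score was taken as the log2 value of Dbp minus that of Arntl. Alternatives set in advance were every probe set tested alone, the mean of a gene's probe sets, quantile normalization, centring on array medians, leaving out dim genes, fitting only the groups compared, the mouse number as a block, array weights, a trended and robust prior, no moderation, other thresholds, other scales of concentration, the air controls split between comparisons, and leaving out each mouse. A covariate for RNA quality from control probe sets was also set in advance and could not be run. The array axis, the quartile range and the clock score as covariates, 1 ppm in place of air, and fits without some groups were added after the data had been seen.

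The pipeline was tested on simulated data with the groups of this study. At 120 ppm against air, 62.7% of 67 genes given a change of 0.5 log2 were recovered, 95.5% of those given 1 log2 and 98.5% of those given 2 log2, with 10 other genes called. In the simulated comparison of 120 with 40 ppm these shares were 49.3%, 92.5% and 98.5%, with 11 other genes called. A simulated group with no change gave 0 calls with limma. The noise was drawn for each gene on its own, without the array-wide differences seen among the real mice. The counts of false calls in these simulations therefore do not carry over to the real data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.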

Results

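The data describe the messenger RNA of whole lung from male CD-1 mice that breathed styrene, a volatile solvent that cytochrome P450 enzymes of the mouse airway turn into a reactive epoxide. The series was designed as a concentration response, with 5 mice in each of 6 groups from 1 to 120 ppm (1, 5, 10, 20, 40, 120) and 5 control mice that breathed air alone. The labels disagree on the exposure: the protocol and the sample titles give 6 hours on 1 day, whereas the series title and the sample characteristics give 5 days. No choice between them is made here, and the length of exposure behind each value is therefore open. The medians of the 35 arrays lay between 4.35 and 4.56 log2.

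The arrays fell into a set of air and 1 ppm and a set of 5 to 120 ppm. Within the second set they did not follow the order of the concentrations. The first principal component, taken over all 45037 probe sets, held 67.3% of the variance and the second 6.88%. The mean score on the first was 0.237 ± 0.0494 (SD, n = 5) in air, 0.265 ± 0.0366 at 1 ppm, -0.200 ± 0.0238 at 5 ppm and -0.105 ± 0.0395 at 120 ppm, so that 5 ppm lay farthest from air. It was -0.0847 at 10 ppm, -0.0483 at 20 ppm and -0.0643 at 40 ppm, so from 20 to 120 ppm the mean moved away from air. Each of the groups from 5 to 120 ppm differed from air on this score in exact permutation tests (p = 0.00794, adjusted p = 0.0115), the smallest p that 252 arrangements allow. The score at 1 ppm did not differ from that in air by the same exact test (p = 0.373, adjusted p = 0.398). The interquartile range of the values on an array was 3.04 ± 0.0917 log2 in air, 2.85 ± 0.117 at 1 ppm, 3.48 ± 0.0512 at 5 ppm and 3.42 ± 0.0207 at 120 ppm. It differed from air at 1 ppm (exact p = 0.0159, adjusted p = 0.0212) and at each concentration from 5 ppm up (exact p = 0.00794, adjusted p = 0.0115). Arrays of air and 5 ppm had a mean correlation of 0.891 across all probe sets, those of air and 120 ppm 0.928, and those within the air group 0.981. The labels give no array date or batch, so a batch that follows the groups cannot be told apart from them.

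**Figure D1:**
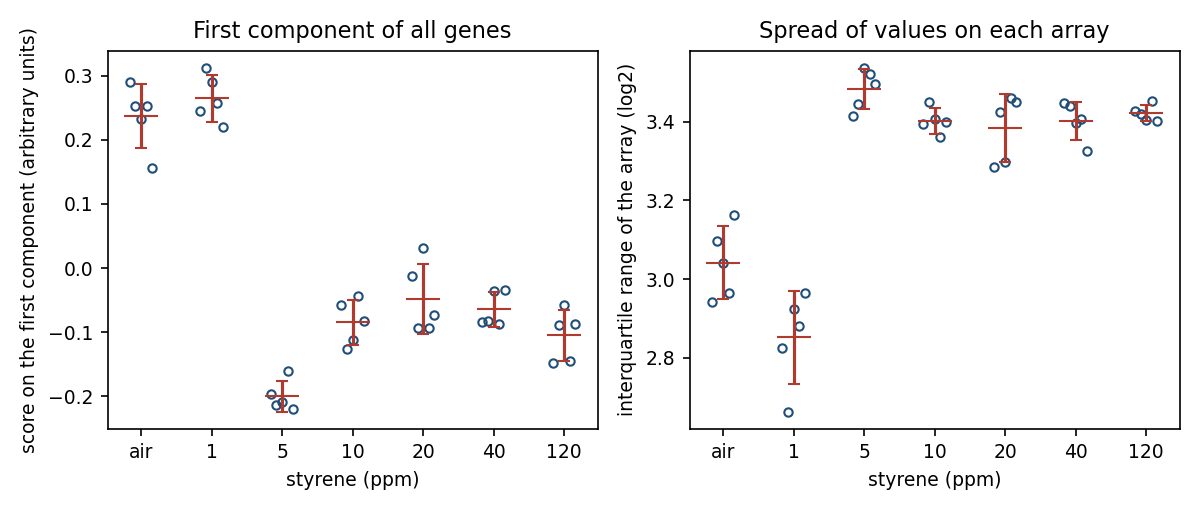
Score on the first principal component of all probe sets (left, arbitrary units) and interquartile range of the log2 values (right) for each array, by styrene concentration in ppm. Circles are the 5 mice of a group, and red marks are the mean with SD. Air and 1 ppm lie apart from the other groups in both panels, and 5 ppm lies farther from air (-0.200) than 120 ppm does (-0.105).

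The comparison of 120 ppm with air asks how lung expression at the highest concentration differed from that of the controls. The largest rises were those of Nr1d2, a repressor of the circadian clock (log2 change 3.08 ± 0.425, SE, n = 5), Drc3, a part of the motor regulator of cilia (2.78 ± 0.239), Chil4, a chitinase-like protein (2.74 ± 0.211), Msh6, a mismatch repair protein (2.71 ± 0.141), and Lrpprc, which binds mitochondrial messenger RNA (2.68 ± 0.185). Tgtp1, an interferon-induced GTPase, rose by 2.67 ± 0.373, and Lin7c, Cxadr, Tspan2 and Hsdl2 by 2.58, 2.57, 2.56 and 2.55. The largest falls held 3 subunits of platelet receptors, Gp1bb (-3.10 ± 0.325), Gp9 (-2.18 ± 0.208) and Itga2b (-2.16 ± 0.188), with Slc4a1, the anion exchanger of red blood cells (-2.41 ± 0.373), Eln, which encodes elastin (-2.31 ± 0.211), and H2-Eb1, a class II antigen-presenting molecule (-2.46 ± 1.03). Spon2 (-2.92), Pkdcc (-2.21), S1pr4 (-2.20) and Ly6d (-2.15) completed them. Drc3 rose in 1 of its 2 probe sets and Cxadr in 4 of 5. The arrays of the 2 groups stood apart on the first component (-0.105 against 0.237). With the array axis as a covariate the calls of Nr1d2 (0.61, adjusted p = 0.536), Spon2 (-1.74, adjusted p = 0.0878), Slc4a1 (-1.57, adjusted p = 0.0996), H2-Eb1 (-1.50, adjusted p = 0.646) and Ly6d (-1.67, adjusted p = 0.147) were lost. The call of H2-Eb1 (adjusted p = 0.0353) was also lost without air mouse 1, 2, 3 or 4 (adjusted p = 0.0663, 0.0654, 0.0737 and 0.0704) and without 120 ppm mouse 2, 3 or 4 (adjusted p = 0.093, 0.0865 and 0.0901).

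Among the cytochrome P450 and other xenobiotic enzymes, 9 of 20 measured members rose at 120 ppm, 1 fell and 10 did not pass the test, with 9 higher and 1 lower when adjusted over the list alone. Aldh1a7 (2.10 ± 0.164), Aox3 (2.09 ± 0.209), Aldh1a1 (1.16 ± 0.135) and Fmo1 (1.11 ± 0.125) rose. Cyp2f2, the main P450 of club cells, which are the secretory cells of the small airways, changed by 0.08 ± 0.0611 (adjusted p = 0.271) from 13.06 ± 0.0711 log2 (SD) in air. Cyp2e1 gave 0.97 ± 0.743 (adjusted p = 0.244), and Cyp2b10 rose by 0.41 ± 0.12 (adjusted p = 0.00297). Of 27 NRF2 targets and glutathione enzymes, 11 rose and 8 fell, and the same counts passed when adjusted over the list alone. Their median was -0.03 and their mean 0.18, and the list test pointed up (adjusted p = 0.754). Over all genes 68.9% were called at 120 ppm, 5096 higher and 6688 lower, so the share called did not set this list apart. Nqo1, a quinone reductase (1.49 ± 0.197, from 4.78 ± 0.435 log2, SD, in air), Gsta4, a glutathione transferase (1.60 ± 0.155, from 8.91 ± 0.427), and Prdx1 (1.17 ± 0.104) rose in all 5 mice, whereas Osgin1 fell (-1.15 ± 0.111). Of 19 club cell markers, 4 rose, 2 fell and 13 did not pass, with 4 and 2 when adjusted over the list alone, and Scgb1a1, the main secretory protein of these cells, gave 0.09 ± 0.0518 (adjusted p = 0.127). Scgb1a1 was called with no moderation, with the trended and robust prior and against 1 ppm (adjusted p = 0.0059, 0.0297 and 0.0472). Once the array axis was a covariate Fmo1 (0.54, adjusted p = 0.0514) and Cyp2b10 (0.08, adjusted p = 0.841) lost their calls and Cyp2e1 gained one (4.51, adjusted p = 0.00603). Cyp2e1 was above the control mean in 3 of 5 mice. Its value with the covariate is extrapolated, because the axis scores did not overlap (lowest 0.646 in air, highest -0.0538 at 120 ppm). Cyp2b10 also lost its call with the quartile range as a covariate (0.29, adjusted p = 0.371).

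Over all 17097 genes 68.9% were called at 120 ppm, 5096 higher and 6688 lower, and camera called 0 of 39 lists. A list with about this share called, such as the clock list, is not set apart by its counts. Markers of ciliated cells and of alveolar macrophages were mostly higher at 120 ppm. In ciliated cells 11 of 16 markers rose and 3 fell, the same when adjusted over the list alone, with rises of Mlf1 (2.29 ± 0.221) and Cdhr3 (1.91 ± 0.214) and a fall of Tppp3 (-0.88 ± 0.105). Of 9 alveolar macrophage markers 6 rose and 0 fell, with both adjustments, among them Chil3 (1.43 ± 0.156), Plet1 (1.38 ± 0.111) and Cd9 (1.20 ± 0.103). Interferon response genes, which lead the antiviral state, rose in 12 of 19 and fell in 2, and Ifit1 rose by 2.17 ± 0.257 and Ddx58 by 1.39 ± 0.128. Immediate early genes, which answer growth and stress signals within minutes, fell in 13 of 19 and rose in 1, with Junb at -1.87 ± 0.18 and Ier2 at -1.40 ± 0.13. Antigen presentation genes fell in 9 of 12 and rose in 1, with H2-DMa at -1.35 ± 0.155 and H2-DMb1 at -1.29 ± 0.164. For each of these last 3 lists the counts were the same when adjusted over the list alone. Among clock genes and their direct output 8 of 18 rose and 4 fell, also over the list alone, including Per3 (2.33 ± 0.449), Per2 (1.89 ± 0.26) and Ciart (1.39 ± 0.213), and Dbp gave 1.78 ± 0.851 (adjusted p = 0.0636, and 0.0396 when only these groups were fitted). The arrays at 120 ppm and in air stood apart beside all of these groups (interquartile range 3.42 against 3.04 log2). Adding the array axis as a covariate, Ifit1 (0.68, adjusted p = 0.204), H2-DMb1 (-0.69, adjusted p = 0.0778) and Per3 (1.51, adjusted p = 0.207) lost their calls.

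Genes of growth control moved both ways at 120 ppm. Cdkn1a, an inhibitor of the cell cycle and target of p53, fell by 1.61 ± 0.309 on the log2 scale. Mki67, a marker of cycling cells, gave 0.28 ± 0.155 (adjusted p = 0.106). It was called higher after quantile normalization (0.35, adjusted p = 0.0489). Of 39 mitosis genes 8 rose and 12 fell, and 7 and 12 when adjusted over the list alone, where 68.9% of all genes were called. In the fibroblast and extracellular matrix list 6 of 16 rose and 5 fell, also over the list alone, with Eln, Col1a1 (-1.71 ± 0.193) and Col5a1 (-1.59 ± 0.152) lower and Fn1, which encodes fibronectin, higher (1.22 ± 0.139). Beside these groups too the first component differed (-0.105 against 0.237). Under the array axis as a covariate Cdkn1a (-0.999, adjusted p = 0.226) and Col1a1 (-0.54, adjusted p = 0.158) lost their calls, and Mki67 turned to -0.45 (adjusted p = 0.203).

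Over all genes, 5096 rose and 6688 fell at 120 ppm, together 11784 of 17097 (68.9%), and 7879 of these moved at least 1.5-fold. The balance of directions depended on the setting: rises outnumbered falls among genes that moved at least 1.5-fold (4204 to 3675), with dim genes left out (4807 to 4225) and with the array axis as a covariate (2158 to 2002). With the array axis as a covariate 4160 genes were called, and with the quartile range 5042. Camera called 0 of 39 lists, with 5 at an unadjusted p under 0.05 and a lowest adjusted p of 0.101. With an estimated correlation it called 0, and fry, which does not compare a list with other genes, called 20 and, under the array axis as a covariate, camera called 3 lists. In the P450 list the adjusted p was 0.101 (0.997 with an estimated correlation), and in the ciliated and macrophage lists it was likewise 0.101.

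**Figure D2:**
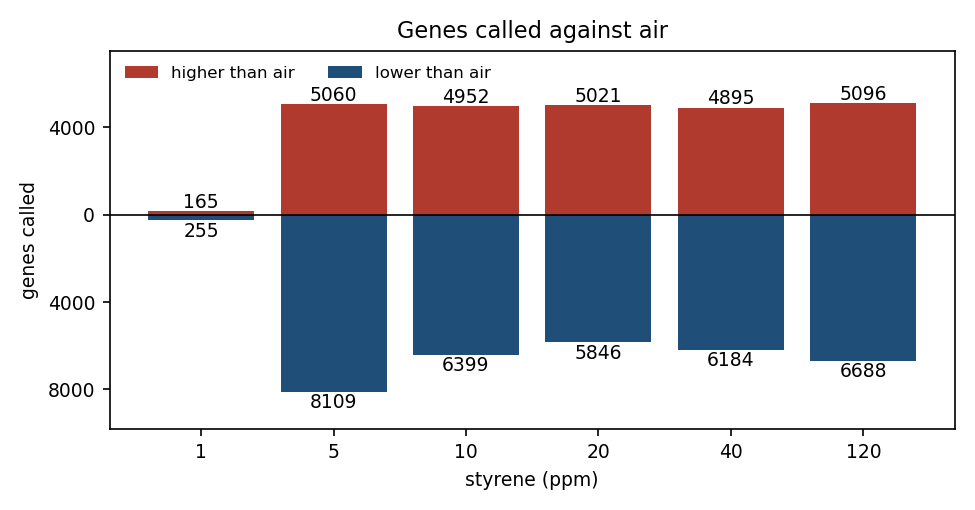
Genes called against air at each styrene concentration in ppm, as counts above 0 for genes higher than air and below 0 for genes lower than air (limma, adjusted p under 0.05, 5 mice a group). The total was 420 at 1 ppm, 13169 at 5 ppm and 11784 at 120 ppm.

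At 40 ppm, the next lower concentration, Drc3 (2.52 ± 0.239), Msh6 (2.47 ± 0.141), Tdrd3, Hsdl2, Insyn2a, Chil4, Copg2, Bbs5, Slu7 and Tspan2 (2.31 to 2.34 for the last 8) made up the largest rises against air. Drc3 rose in 1 of its 2 probe sets, Insyn2a in 1 of 3 and Slu7 in 6 of 7. Gp1bb (-2.31 ± 0.325), Pkdcc (-2.17 ± 0.269), Ly6d (-2.13 ± 0.434), Itga2b (-2.04 ± 0.188) and Krtap17-1 (-2.00 ± 0.209) led the falls, followed by Ncdn (-1.97), Sbk1 (-1.93), Gp9 (-1.93), Slc4a1 (-1.91) and Pex16 (-1.89, in 2 of 3 probe sets). Over all genes 64.8% were called at 40 ppm. Of the P450 and other xenobiotic enzymes 10 rose and 1 fell, and 9 and 1 when adjusted over the list alone, with Aldh1a7 at 1.77 ± 0.164 and Aox3 at 1.87 ± 0.209. Of the NRF2 targets and glutathione enzymes 10 rose and 9 fell, and 10 and 10 over the list alone, with a median of -0.08, a mean of 0.07 and a list test that pointed up. Nqo1 rose by 1.33 ± 0.197, Gsta4 by 1.29 ± 0.155 and Prdx1 by 1.12 ± 0.104, and Osgin1 fell (-1.39 ± 0.111). Cyp2f2 gave -0.01 ± 0.0611 (adjusted p = 0.838), Cyp2e1 1.18 (adjusted p = 0.164), Cyp2b10 0.22 (adjusted p = 0.11), Scgb1a1 0.10 (adjusted p = 0.103, but 0.00334 with no moderation, 0.0201 with the trended and robust prior and 0.0364 against 1 ppm), Mki67 0.05 (adjusted p = 0.802) and Dbp -0.28 (adjusted p = 0.785). Cyp2f2 and Mki67 took the opposite sign under quantile normalization (0.05) and median centring (-0.01), respectively. Against 1 ppm Mki67 was called lower (-0.40, adjusted p = 0.0223). Cdkn1a fell by 0.79 ± 0.309 (adjusted p = 0.0263), lower in 3 of 5 mice. The arrays at 40 ppm stood apart from air on the first component (-0.0643 against 0.237).

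In the same comparison 10 of 16 ciliated cell markers rose and 2 fell, with Mlf1 at 1.84 ± 0.221 and Cdhr3 at 1.67 ± 0.214. Alveolar macrophage markers rose in 6 of 9, with Plet1 at 1.15 ± 0.111 and Cd9 at 1.18 ± 0.103. Immediate early genes fell in 11 of 19, with Junb at -1.89 ± 0.18 and Ier2 at -1.32 ± 0.13, and interferon response genes rose in 11 of 19 and fell in 2, with Ifit1 at 1.91 ± 0.257 and Oasl2 at 1.72 ± 0.225. For these 4 lists the counts did not differ when adjusted over the list alone. Antigen presentation genes fell in 9 of 12, and 9 fell and 1 rose over the list alone, with H2-DMa at -1.26 ± 0.155. The interquartile range of the arrays was 3.402 log2 at 40 ppm and 3.04 in air beside all of these groups. Over all genes 4895 rose and 6184 fell (11079, 64.8%), with 7290 at least 1.5-fold, 5166 with the array axis and 4830 with the quartile range as a covariate. Rises outnumbered falls at 1.5-fold (3924 to 3366), with dim genes left out (4730 to 4038) and with the array axis (2742 to 2424). Camera called 0 lists, with 8 at an unadjusted p under 0.05, a lowest adjusted p of 0.199, 0 with an estimated correlation and 19 by fry. The calls of Slc4a1 (-1.22, adjusted p = 0.133), Ly6d (-1.73, adjusted p = 0.0683), Cdkn1a (-0.29, adjusted p = 0.728) and Ifit1 (0.69, adjusted p = 0.12) were lost with the array axis as a covariate, and Cyp2e1, above the control mean in 4 of 5 mice, gained one (4.09, adjusted p = 0.00346, extrapolated beyond the axis scores shared by the groups). That of Cdkn1a was also lost without air mouse 2 (adjusted p = 0.0656) and without 40 ppm mouse 1, 4 or 5 (adjusted p = 0.0532, 0.112 and 0.107).

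Calls at 40 and 120 ppm overlapped in 10334 genes, of which 4620 were higher in both and 5714 lower in both, and 0 were called in opposite directions. Because both comparisons used the same air mice, the overlap was recounted with the controls split between them, which gave 7920 to 8797 genes over 20 splits. Both parts of the split controls lay on the same side of the gap between arrays, so the recount does not separate an array-wide difference from exposure. The overlap of 2 unchanged simulated groups was 0. Unchanged groups give few calls to share, so this 0 does not measure what shared controls add when this many genes are called. Independent lists of the sizes called without a covariate would share 3878. With the array axis as a covariate 3832 were shared. Fewer genes were called at each concentration with that covariate, so 3878 is not the count to set beside 3832.

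At 5 ppm more genes were called against air than at any other concentration, but with the array axis as a covariate fewer were called than at 10, 20, 40 or 120 ppm. The largest rises were those of Iigp1, an interferon-inducible GTPase (3.49), Hltf, a chromatin remodeller (3.48), Gbp10, a guanylate-binding protein (3.45), Zfp280d (3.42, in 1 of 2 probe sets) and Lin7c (3.398). Gp1bb (-2.68), Ocel1 (-2.64), Armc6 (-2.62), Gchfr (-2.57) and Itga2b (-2.50) fell most. Mki67 rose by 2.23 ± 0.155, Gsta4 by 1.13 ± 0.155 and Nqo1 by 0.71 ± 0.197. Of 19 interferon response genes 12 rose and 2 fell, also over the list alone, with a camera adjusted p of 0.074 (0.991 with an estimated correlation). In the 5 ppm group 5060 genes rose and 8109 fell (13169, 77.0% of all genes), and the median of all genes was -0.23, or -0.33 after centring each array on its median. The balance was nearly even with dim genes left out (4601 higher, 4780 lower) and among genes that moved at least 1.5-fold (4287 higher, 4739 lower). The first component lay at -0.200 against 0.237 in air, and with the array axis as a covariate 2777 genes were called and the calls of Iigp1 (2.11, adjusted p = 0.12), Gbp10 (1.45, adjusted p = 0.348), Hltf (1.25, adjusted p = 0.133), Zfp280d (1.05, adjusted p = 0.214), Nqo1 (1.02, adjusted p = 0.146), Ocel1 (-1.14, adjusted p = 0.378), Armc6 (-0.88, adjusted p = 0.107) and Gchfr (-0.09, adjusted p = 0.902) were lost. With the quartile range 5836 genes were called, and under quantile normalization Nqo1 was not called (0.42, adjusted p = 0.113). Camera called 0 lists (6 at an unadjusted p under 0.05, 0 with an estimated correlation), and fry 19.

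The difference between 5 and 10 ppm was tested directly after the data had been seen: 1685 genes were higher at 5 ppm and 2973 lower (4658), and among those that moved at least 1.5-fold 1124 were higher and 349 lower. Interferon response genes were higher at 5 ppm as a list (7 of 19 rose and 0 fell, also over the list alone, camera adjusted p = 0.000101), and so were mitosis genes (10 of 39 rose and 0 fell, also over the list alone, adjusted p = 0.00577). Both calls were lost with an estimated correlation (adjusted p = 0.997 for each). The 2 groups also stood apart on the first component (-0.200 against -0.0847).

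At 10 ppm Tspan2 (2.50), Taf15 (2.45), Msh6 (2.44), Cxadr (2.41, in 3 of 5 probe sets) and Lin7c (2.38) rose most against air. Ly6d (-2.49) and Gp1bb (-2.27) fell, as did Ckm (-2.33), Mb (-2.29) and Pgam2 (-2.03), which are abundant in striated muscle. Nqo1 rose by 1.19 ± 0.197 and Gsta4 by 1.07 ± 0.155. At 20 ppm Drc3 (2.59), Bbs5 (2.53), Msh6 (2.52), Chil4 (2.42) and Cd55 (2.39) rose most, and Gp1bb (-2.24), Ckm (-2.10), Ly6d (-2.00), S1pr4 (-1.98) and Armc6 (-1.94) fell most. Nqo1 rose there by 1.71 ± 0.197 and Gsta4 by 1.43 ± 0.155. The first component lay at -0.0847 at 10 ppm and -0.0483 at 20 ppm, against 0.237 in air. With the array axis as a covariate the muscle genes at 10 ppm turned to 0.01 (Ckm), 0.20 (Mb) and 0.36 (Pgam2), Ckm at 20 ppm became -0.16 (adjusted p = 0.908), and Ly6d lost its call at 10 ppm (adjusted p = 0.0561) and at 20 ppm (adjusted p = 0.0742). With the quartile range these genes also lost their calls (adjusted p = 0.216 for Ckm, 0.29 for Mb and 0.159 for Pgam2 at 10 ppm, and 0.27 for Ckm and 0.0756 for Ly6d at 20 ppm). The numbers called were 11351 at 10 ppm (4952 higher, 6399 lower) and 10867 at 20 ppm (5021 higher, 5846 lower), and with the array axis 4081 and 5194. Rises outnumbered falls in both groups among genes that moved at least 1.5-fold (3970 to 3543 and 3943 to 3100), with dim genes left out (4743 to 4171 and 4789 to 3887) and with the array axis (2130 to 1951 and 2857 to 2337). At both concentrations camera called 0 lists (8 each at an unadjusted p under 0.05, 0 with an estimated correlation) and fry called 16.

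At 1 ppm, the lowest concentration, Tyms-ps (0.97 ± 0.167), Slc22a21 (0.93), Lmx1a (0.93), Ces2a, a carboxylesterase (0.91), and Csmd2os (0.77) rose most against air, and Tmem71 (-1.43 ± 0.262), Plekhg1 (-1.13), Abhd10 (-0.96), Taf5 (-0.95) and Stk38l (-0.93) fell most. With the mean of its probe sets Stk38l was not called (-0.32, adjusted p = 0.18). In the 39 lists 1 mitosis gene was called lower and 1 thymocyte marker higher, where 2.46% of all genes were called. Limma called 165 genes higher and 255 lower (420, with 2664 at an unadjusted p under 0.05), and 120 of them moved at least 1.5-fold. Which direction prevailed depended on the setting, with 211 higher and 140 lower after quantile normalization, 168 and 151 after centring, and 9 and 166 with dim genes left out. The quartile range of the arrays was 2.85 log2 against 3.04 in air, and with it as a covariate Tmem71 (adjusted p = 0.148), Plekhg1 (adjusted p = 0.0701), Ces2a (adjusted p = 0.143) and Csmd2os (adjusted p = 0.219) were not called. In a fit of these groups alone 3 genes were called, and Tyms-ps, Slc22a21, Lmx1a, Ces2a, Csmd2os, Tmem71 and Stk38l were not (adjusted p from 0.116 to 0.509). The count was 197 without air mouse 2, 275 without air mouse 3, 254 without air mouse 5, 179 without 1 ppm mouse 2 and 687 without 1 ppm mouse 3. Ces2a was not called without air mouse 2, 3 or 5 or 1 ppm mouse 1, 2 or 3 (adjusted p = 0.0605, 0.0786, 0.0594, 0.0994, 0.054 and 0.0783). Camera called 0 lists, with 6 at an unadjusted p under 0.05, 0 with an estimated correlation and 0 by fry.

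The comparison of 120 with 40 ppm asks how the highest concentration differed from the next, and its arrays overlapped on the first component (-0.105 against -0.0643, exact p = 0.0873, adjusted p = 0.0998). The 3 genes called all belong to the extracellular matrix and its turnover and were lower at 120 ppm in all 5 mice: Eln, elastin (-1.30 ± 0.211, adjusted p = 0.0103), Mrc2, a collagen uptake receptor (-0.71 ± 0.119, adjusted p = 0.0103), and Loxl1, which crosslinks elastin (-0.70 ± 0.131, adjusted p = 0.0462). Mean Eln expression was 10.05 log2 in air, 10.39 at 1 ppm, 8.81 at 5 ppm, 9.03 at 40 ppm and 7.73 at 120 ppm. Low values were not particular to 120 ppm, since Mrc2 averaged 7.27 at 5 ppm and 7.28 at 120 ppm, and Loxl1 9.04 and 8.89. In the fibroblast and extracellular matrix list 13 of 16 genes had lower values at 120 ppm, 1 of them called over all genes and 9 when adjusted over the list alone, among them Col1a1 (-0.99 ± 0.193, adjusted p = 0.0573 over all genes) and Col5a1 (-0.72 ± 0.152, adjusted p = 0.0718). Col1a1 was called over all genes with array centring, with dim genes left out, with array weights, with the trended and robust prior and in the 10 to 120 ppm groups alone (adjusted p = 0.0273, 0.0406, 0.0033, 0.029 and 0.0108). Array weights also gave calls for Col5a1 and Cdh5 (0.00662 and 0.0278). The list fell as a whole (median -0.33, camera adjusted p = 1.96e-10, fry adjusted p = 1.05e-05), also with an estimated correlation (adjusted p = 0.000948). Endothelial markers had lower values in 13 of 15 (median -0.34, camera adjusted p = 5.22e-07), 0 called over all genes and 7 over the list alone, such as Cdh5, a junction protein of vessels (-0.42 ± 0.109, adjusted p = 0.186). That list kept its call with an estimated correlation (adjusted p = 0.0382).

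Smooth muscle markers were lower in 8 of 8 (median -0.36, camera adjusted p = 1.65e-05, adjusted p = 0.06 with an estimated correlation), with 3 called over the list alone. Clock genes were higher in 14 of 18 (median 0.42, camera adjusted p = 0.000272, adjusted p = 0.06 with an estimated correlation), and 5 were called higher and 1 lower over the list alone, with Nr1d2 at 1.33 ± 0.425 (adjusted p = 0.287 over all genes) and the clock activator Arntl at -1.46 ± 0.4 (adjusted p = 0.228). Camera also called cholesterol synthesis (19 of 20 lower, adjusted p = 0.000817), glucocorticoid targets (14 of 17 lower, adjusted p = 0.00259) and red blood cells (6 of 6 lower, adjusted p = 0.0352) in the downward direction. NRF2 targets and glutathione enzymes (22 of 27 higher, adjusted p = 0.0044) and club cell markers (17 of 19 higher, adjusted p = 0.0044) were called in the upward direction. In these 5 lists 0 genes were called, over all genes or over the list alone, and with an estimated correlation the calls were lost (adjusted p = 0.281, 0.638, 0.396, 0.638 and 0.638). Cyp2f2 (0.09), Gsta4 (0.31, adjusted p = 0.532), Cdkn1a (-0.82, adjusted p = 0.376) and Dbp (2.05, adjusted p = 0.439) did not pass.

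Limma called 0 genes higher and 3 lower between 120 and 40 ppm (1625 at an unadjusted p under 0.05), and 0 when only these groups were fitted, with the clock score as a covariate or with the mean of a gene's probe sets. The call of Eln was lost without 40 ppm mouse 3 (adjusted p = 0.0502) or 120 ppm mouse 3 or 4 (adjusted p = 0.0682 and 0.0754). That of Mrc2 was lost without 40 ppm mouse 1, 3 or 4 (adjusted p = 0.0691, 0.0502 and 0.0534) or 120 ppm mouse 3 or 4 (adjusted p = 0.0682 and 0.102). That of Loxl1 held without 120 ppm mouse 2, and was lost without 40 ppm mouse 1, 2, 3, 4 or 5 (adjusted p = 0.131, 0.108, 0.252, 0.0679 and 0.0729) or 120 ppm mouse 1, 3, 4 or 5 (adjusted p = 0.0735, 0.079, 0.424 and 0.135). The count was 1 without 40 ppm mouse 1 or 4, 0 without 40 ppm mouse 3 or 120 ppm mouse 3 or 4, and 14 without 120 ppm mouse 2. The glucocorticoid list lost its call without 40 ppm mouse 2 (adjusted p = 0.0689), and the red blood cell list without 40 ppm mouse 3 or 4 or 120 ppm mouse 3 or 5 (adjusted p = 0.0539, 0.115, 0.0928 and 0.0868).

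**Figure D3:**
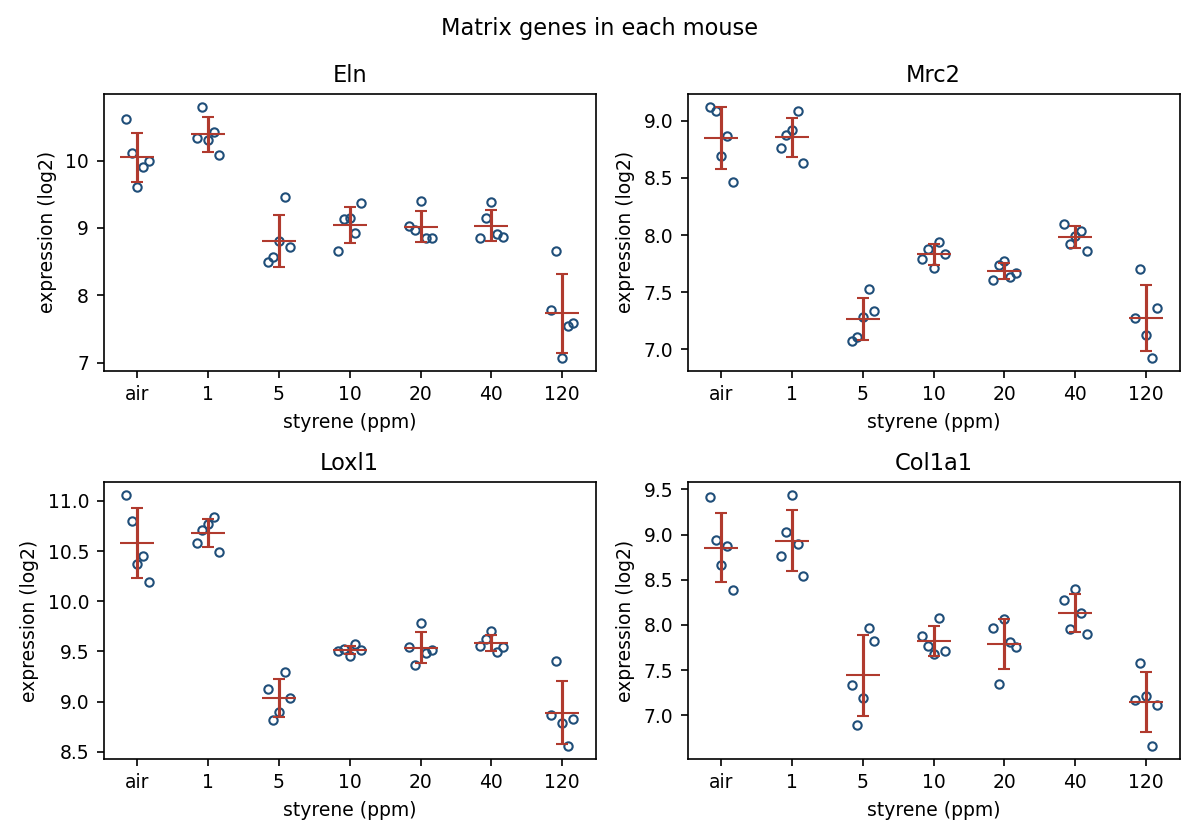
Log2 expression of Eln, Mrc2, Loxl1 and Col1a1 in each mouse (circles) by styrene concentration in ppm, with the group mean and SD in red. Eln averages 10.05 in air, 8.81 at 5 ppm, 9.03 at 40 ppm and 7.73 at 120 ppm, and Mrc2 is as low at 5 ppm (7.27) as at 120 ppm (7.28).

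Since air and 1 ppm stood apart, 120 ppm was also compared with the 10, 20 and 40 ppm groups together, a comparison added after the data had been seen. Matrix genes were again lower: Eln (-1.30 ± 0.173, adjusted p = 0.000216), Loxl1 (-0.66 ± 0.107, adjusted p = 0.00404), Mrc2 (-0.56 ± 0.0969, adjusted p = 0.0097), Col3a1 (-0.35, adjusted p = 0.0314), Col1a1 (-0.77 ± 0.157, adjusted p = 0.0323) and Col5a1 (-0.60, adjusted p = 0.0338). Col4a1, Col4a2, Mmp14, Adm, a vasodilator peptide (-1.25 ± 0.24, adjusted p = 0.0207), Hnrnpl, Scarf2, Thra and Rhob also fell. The 2 rises were those of Mthfd1l, a mitochondrial folate enzyme (0.90, adjusted p = 0.0272), and Lonrf1 (0.56, adjusted p = 0.0394). The matrix list fell (12 of 16 lower, 4 called over all genes, 9 over the list alone, camera adjusted p = 1.06e-07, adjusted p = 0.00641 with an estimated correlation). The clock list rose (13 of 18 higher, 0 called over all genes, 9 higher and 3 lower over the list alone, camera adjusted p = 5.28e-05, adjusted p = 0.0364 with an estimated correlation). Its members included Nr1d2 (1.48, adjusted p = 0.0707), Per3 (1.41), Hlf (1.11, adjusted p = 0.0603), Dbp (2.25, adjusted p = 0.226) and, in the other direction, Arntl (-1.47, adjusted p = 0.0603). With array weights Arntl, Nr1d2 and Hlf were called (0.0311, 0.039 and 0.0355). Arntl and Hlf were called with dim genes left out (0.0414 for each), Hlf with the trended and robust prior (0.0477), and Per3 with each probe set alone (0.0346). With the mouse number as a block Dbp, Arntl, Nr1d2, Per3 and Hlf were called, as set out with the processing settings below. The first component was -0.105 at 120 ppm and -0.0847, -0.0483 and -0.0643 at 10, 20 and 40 ppm.

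Camera called 11 other lists between 120 ppm and these groups, each lost with an estimated correlation. The xenobiotic enzymes (adjusted p = 0.00287, 0.373 with an estimated correlation), interferon response (0.00456 and 0.547), club cell (0.00585 and 0.587), B cell (0.014 and 0.612) and fat tissue lists (0.0433 and 0.759) were higher. The endothelial (0.000502 and 0.171), glucocorticoid (0.00111 and 0.462), red blood cell (0.00408 and 0.171), cholesterol (0.0067 and 0.462), smooth muscle (0.00818 and 0.458) and mitosis lists (0.009 and 0.462) were lower. In these 11 lists 0 genes were called by limma over all genes. Over the list alone 6 endothelial, 3 red blood cell, 2 smooth muscle, 2 mitosis and 1 glucocorticoid gene were called lower, 1 interferon gene was called higher, and 0 genes of the other 5 lists were called. Without 120 ppm mouse 3 the mitosis (adjusted p = 0.065), cholesterol (0.0536), B cell (0.255) and fat tissue lists (0.549) were not called. The B cell list was also lost without 120 ppm mouse 4 (0.0696), and the fat tissue list without 10 ppm mouse 2, 3 or 5 (0.0788, 0.0595 and 0.133), 20 ppm mouse 2, 3, 4 or 5 (0.0542, 0.0531, 0.0644 and 0.0522) or 40 ppm mouse 2, 4 or 5 (0.072, 0.0634 and 0.0658).

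Limma called 2 genes higher and 14 lower at 120 ppm than at 10 to 40 ppm (1836 at an unadjusted p under 0.05). The count was 5 with the array axis as a covariate, 0 with the clock score, 52 when only these groups were fitted, 3, 1 and 5 without 120 ppm mouse 3, 4 or 5, and 61 without mouse 2. Eln kept its call without any 1 mouse, and without 120 ppm mouse 4 the other 15 lost theirs (adjusted p from 0.0902 for Hnrnpl to 0.484 for Lonrf1). Without mouse 3 all but Eln, Loxl1 and Hnrnpl lost theirs (adjusted p from 0.0775 to 0.142), and without mouse 5 all but these, Mrc2 and Scarf2 did (0.0818 to 0.169). Col1a1, Col5a1 and Rhob also lost theirs without 120 ppm mouse 1 (0.0725, 0.0566 and 0.0641). These 3 genes, Col3a1 and Lonrf1 lost theirs without 10 ppm mouse 4, 20 ppm mouse 3, or 40 ppm mouse 1 or 3 (0.0514 to 0.072), and Lonrf1 also without 10 ppm mouse 3 or 5, 20 ppm mouse 1 or 2, or 40 ppm mouse 2 or 5 (0.0516 to 0.059). Between the lower groups limma called 0 genes, both for 20 against 10 ppm (1589 at an unadjusted p under 0.05) and for 40 against 10 ppm (411). Camera at its preset correlation nevertheless called 6 and 3 lists there, with 0 in each case with an estimated correlation or by fry, so calls at the preset correlation also arose between groups with 0 genes called.

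**Figure D4:**
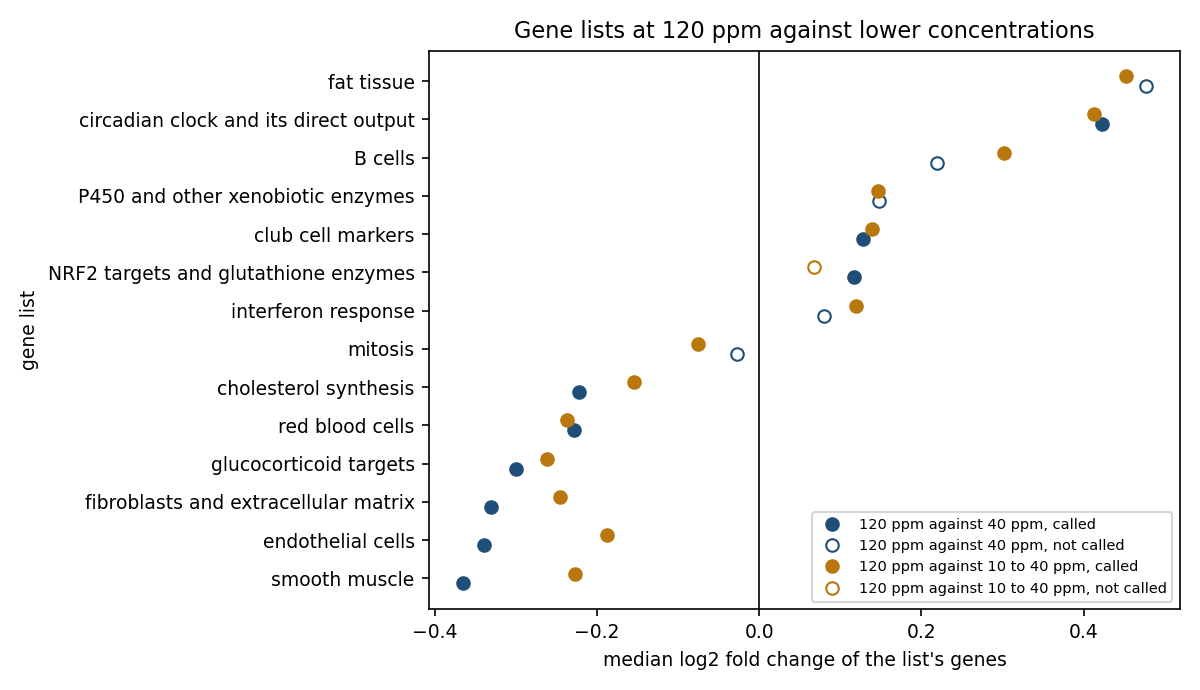
Median log2 fold change of each gene list called by camera (filled) at 120 ppm against 40 ppm or against 10 to 40 ppm together; open circles are lists not called in that comparison. The matrix list lies at -0.33 and -0.25 and the clock list at 0.42 and 0.41; with an estimated correlation the matrix and endothelial lists kept their calls against 40 ppm, the matrix and clock lists kept theirs against 10 to 40 ppm, and all other filled circles lost theirs, the clock list against 40 ppm included (adjusted p = 0.06).

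**Figure D5:**
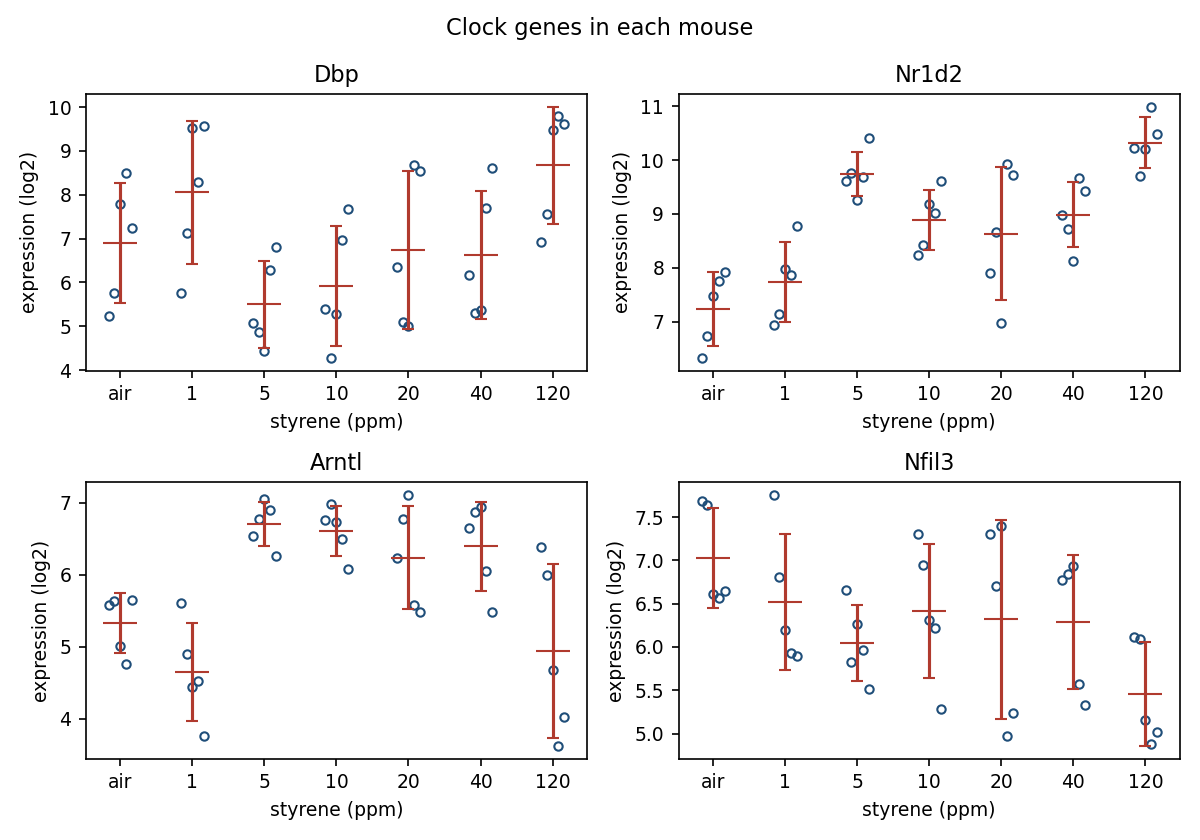
Log2 expression of Dbp, Nr1d2, Arntl and Nfil3 in each mouse (circles) by styrene concentration in ppm, with the group mean and SD in red. Dbp averages 6.90 in air, 6.63 at 40 ppm and 8.68 at 120 ppm, and Arntl 5.33, 6.40 and 4.94.

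A trend over all concentrations asks which genes follow the concentration. The smallest adjusted p among rises belonged to Serpind1, heparin cofactor II (0.33 per unit of log2 concentration), Acad9, a mitochondrial dehydrogenase (0.29), Gstk1, a glutathione transferase (0.28), Mccc1 (0.24) and Phyh, a peroxisomal enzyme of fatty acid oxidation (0.31). Among falls they were Trim41 (-0.12), Eln (-0.32), Gramd1a (-0.19), Glipr2 (-0.23) and Niban2 (-0.17). Nqo1 (0.25) and Gsta4 (0.26) rose. Camera called 2 lists, the xenobiotic enzymes (12 of 20 rose and 0 fell, 10 and 0 over the list alone, adjusted p = 0.0204) and the ciliated cell markers (11 of 16 rose and 3 fell, also over the list alone, adjusted p = 0.0378), and both were lost with an estimated correlation (adjusted p = 0.824 and 0.856). The trend took in 5275 rises and 7145 falls (12420), and 14083 genes differed among the groups by the F test. Because air and 1 ppm stood apart on the first component (0.237 and 0.265), the trend was refitted without them and called 1 gene, and it called 4842 with the array axis and 14 on linear ppm. Rises outnumbered falls with the array axis (3238 to 1604), with dim genes left out (4989 to 3942) and on linear ppm (10 to 4). Without air and 1 ppm the calls of Eln (adjusted p = 0.0976), Acad9 (0.059), Gstk1 (0.0859), Mccc1 (0.135), Phyh (0.0832), Trim41 (0.295), Gramd1a (0.372), Glipr2 (0.139), Niban2 (0.588), Nqo1 (0.122) and Gsta4 (0.0832) were lost. On linear ppm the calls of these genes were lost as well (adjusted p = 0.0745), except those of Eln and Glipr2, and with the mean of its 2 probe sets Trim41 turned to a rise (0.09).

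Over 10 to 120 ppm alone, a trend added after the data had been seen, limma called 0 genes (1369 at an unadjusted p under 0.05, lowest adjusted p = 0.109). Serpind1 (0.31), Hnrnpl (-0.13) and Eln (-0.38) had adjusted p-values of 0.109, 0.109 and 0.128. Serpind1 was called with array weights (0.0101) and Hnrnpl with the array axis (0.0356). As a list the xenobiotic enzymes rose with the concentration (18 of 20 positive, 0 called over all genes or over the list alone, median 0.05, camera adjusted p = 0.000171), also with an estimated correlation (adjusted p = 0.0353). Camera called 12 lists in all, of which this was the 1 that held with an estimated correlation. On linear ppm 17 genes were called, 16 of them falls, among them Hnrnpl and Eln (adjusted p = 0.00437 for each).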

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

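The gap test for far samples and the count after quantile normalization were set in advance; the other tests weighed in this part, the regroupings of the mice included, were written down after the results they measure had been seen. A sample far from the others of its group was sought in 91 groups of 5 mice over 13 measures, and 0 groups had a gap above the critical value of 0.71. A signal was present in probe sets that the gene tests left out. Of 15588 probe sets with no gene name here, limma called 7610 at 120 ppm against air, 3373 higher and 4237 lower, and of 551 with several gene names it called 352, 165 higher and 187 lower. Between 120 and 40 ppm 4 of the probe sets without a name were called, all lower, and between 120 and 10 to 40 ppm also 4, all lower.

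The arrays of air and 1 ppm lay apart from those of 5 to 120 ppm. Against an effect that grows at each step as the whole cause, the first component at 120 ppm lay 0.0952 above that at 5 ppm, nearer to air. That difference had an exact two-sided permutation p of 0.00794, the smallest that 252 arrangements allow (adjusted p = 0.0115). From 20 to 120 ppm the mean score moved away from air (-0.0483, -0.0643 and -0.105). A growing effect beneath another difference between the groups therefore stays open. Against differences of scale left by the normalization, 10710 genes were called at 120 ppm after quantile normalization. An array-wide technical difference stays open. Across genes, which are not independent replicates, the main axis of the spread within the 10 to 120 ppm groups correlated with the change at 120 ppm against air (size 0.607, sign arbitrary). The size was 0.554 for 20 against 10 ppm and 0.516 for 40 against 10 ppm, where 0 genes were called. The correlation therefore does not single out the gap from air and decides nothing. Whether probe sets of 1 gene answered differently to labelling cannot be told apart, because they went opposite ways in 12.7% of 4219 genes at 120 ppm, 0.954% of 1467 genes between 5 and 10 ppm, and also 11.5% of 26 genes at 1 ppm, whose arrays did not stand apart on the first component. An effect of styrene that does not grow with the concentration stays open too, and a processing batch that follows the groups cannot be told apart from exposure, because the labels give no batch.

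Clock genes at 120 ppm stood apart from those at 10 to 40 ppm, with a clock score (log2 Dbp minus log2 Arntl) higher by 3.72 ± 1.06 (SE, exact two-sided permutation p = 0.00387 over 15504 arrangements, on genes picked after their values had been seen). Against the array-wide difference as the whole cause, the score was higher by 3.42 ± 1.11 with the array axis as a covariate. A difference in the time of death stays open: within groups Dbp and Arntl went opposite ways over 35 mice (Pearson r = -0.857, Spearman rho = -0.912, permutation p = 1e-04 for each, the smallest that the permutations can give, and r = -0.841 without the 2 mice farthest from the median of Dbp), as genes of opposite phase would if mice differed in clock time. The labels give no times, and an effect of styrene on the clock stays open as well. The score was 1.57 ± 1.73 (SD, n = 5) in air, 3.41 ± 2.28 at 1 ppm and -1.21 ± 1.22 at 5 ppm. It was -0.69 ± 1.71 at 10 ppm, 0.50 ± 2.51 at 20 ppm, 0.23 ± 2.08 at 40 ppm and 3.74 ± 2.53 at 120 ppm. Over all groups the score did not follow the concentration, but from 5 to 120 ppm its mean rose at each step except from 20 to 40 ppm. For the clock list between 120 and 40 ppm, 17 of 126 splits of the 10 mice gave a camera p as small (real 2.79e-05, smallest other 2.25e-09), so these splits, which take no account of the mouse numbers, do not exclude chance.

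Matrix genes were lower at 120 than at 40 ppm. Against the array-wide difference as the whole cause of the list's fall, its adjusted p with the array axis as a covariate and an estimated correlation was 0.00078. With the clock score as a covariate and an estimated correlation it was 0.00202. Over the list's settings with an estimated correlation the adjusted p ran from 0.00078 to 0.00202. With the clock score the gene calls ended because each fold was smaller against its error and missed the threshold adjusted over all genes. Most of the fold remained (Eln from -1.30 ± 0.211 to -1.04 ± 0.218, Mrc2 from -0.71 ± 0.119 to -0.62 ± 0.131, Loxl1 from -0.70 ± 0.131 to -0.57 ± 0.141, adjusted p = 0.339, 0.339 and 0.55). The score rests on Dbp and Arntl alone and may adjust for clock time only in part. What remains of the list and the folds therefore does not decide whether the clock is the whole cause. Fewer fibroblasts cannot be told apart, although the mean of 4 fibroblast markers changed by -0.07 (exact two-sided permutation p = 0.722) and that of the 12 other members by -0.48 (exact p = 0.00794, the smallest that 252 arrangements allow), because their difference of -0.41 had an exact p of 0.0556, and an effect of styrene stays open. For the list, 2 of 126 splits of the 10 mice gave a camera p as small (real 5.02e-12, smallest other 6.79e-13). The list was taken up after its result had been seen, so these splits do not exclude chance.

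Regrouping the mice tested whether chance could give the counts, with 100 splits each. The real split alone reached the count for 5 ppm (13169 genes, highest other 10616, 1 split as large), 10 ppm (11351, 9379, 1), 20 ppm (10867, 9477, 1), 40 ppm (11079, 8864, 1) and 120 ppm (11784, 9641, 1). The same held for the trend (12420, highest other 0, 1), for any difference (14083, 6456, 1) and for the overlap of 40 and 120 ppm (10334, 4999, 1). For these counts the splits argue against chance, at an unadjusted share of 1 in 100, the smallest they allow. Few splits reached the count for 120 against 40 ppm (3, highest other 31, 2) and for 120 against 10 to 40 ppm (16, highest other 438, 2). These shares were not adjusted over the tests, and in each case a regrouping called more genes. The comparison with 10 to 40 ppm was also added after the data had been seen, so chance stays open for both. Chance is not excluded for 1 ppm (420, highest other 1737, 13) or for the lists between 120 and 40 ppm (9, 23, 78) and between 120 and 10 to 40 ppm (13, 18, 20). For the lists at 40 and 120 ppm by camera (highest other 14 for each) and the trend over 10 to 120 ppm by limma (highest other 1) the real count was 0, which all 100 splits reach, so the splits decide nothing. Splits that called several times the real count, 1737 at 1 ppm, 31 between 120 and 40 ppm and 438 between 120 and 10 to 40 ppm, point to a structure of the mice other than their groups.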

How the results depend on the processing

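The array axis, quartile range, clock score, 1 ppm as reference, fits of some groups and all settings for results beyond those set in advance were chosen after the data had been seen. The cause was not tested unless a setting's construction (fewer mice, fewer genes) gives it. Counts under settings not named stayed within 1.5 times the reported count, and gene calls kept their direction and side of the threshold in 3395 values, were lost in 204, gained in 40 and reversed in 24. Lists kept their call in 192 values, lost it in 48 and reversed in 2. The RNA quality covariate was not run, because the table holds no control probe sets, so RNA quality is untested; dim genes near the background limit the folds, and leaving dim genes out gave 175 calls at 1 ppm and 33 between 120 and 10 to 40 ppm.

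At 1 ppm (420) each probe set alone gave 746, only the groups compared 3, array weights 76, at least 1.5-fold 120, an adjusted p under 0.1 772, the array axis 643 and the quartile range 78. With the array axis 5, 10, 20, 40 and 120 ppm gave 2777, 4081, 5194, 5166 and 4160, and with the quartile range 5836, 4922, 4816, 4830 and 5042; at least 1.5-fold gave 7513, 7043 and 7290 at 10, 20 and 40 ppm. For 120 against 40 ppm (3) the mean of probe sets gave 0, centring 6, only the groups compared 0, array weights 79, the trended and robust prior 5, an adjusted p under 0.1 19, the clock score 0 and the 10 to 120 ppm groups alone 11. For 120 against 10 to 40 ppm (16) the mean of probe sets gave 9, only the groups compared 52, array weights 77, the trended and robust prior 29, at least 1.5-fold 6, an adjusted p under 0.1 58, the array axis 5 and the clock score 0. The trend (12420) gave 4842 with the array axis, 14 on linear ppm and 1 without air and 1 ppm. Over 10 to 120 ppm it gave 1 with array weights, 2 with the array axis and 17 on linear ppm. The F test (14083) gave 6461 with the array axis, 29 in the 10 to 120 ppm groups and 6985 without air and 1 ppm. The overlap gave 3832 with the array axis. Lists gave 20 by fry and 3 with the array axis at 120 ppm, 19 by fry at 40 ppm, 2 with an estimated correlation and 4 by fry for 120 against 40 ppm, and 2, 4 and 20 (array axis) for 120 against 10 to 40 ppm. The mouse number as a block gave 32 for 120 against 10 to 40 ppm; 46 of 105 pairs of same-numbered mice correlated above 0.1 (mean 0.049, against -0.0115 for other pairs), and 16 of 35 mice correlated best with their own number, so over all genes the numbers were not taken as pairs, although the clock score followed them. With the block the clock genes Dbp, Arntl, Nr1d2, Per3 and Hlf were called against 10 to 40 ppm (adjusted p = 0.0104, 0.00449, 0.00425, 0.00672 and 0.00116) and Dbp at 120 ppm against air (0.00277), and Loxl1 was not called against 40 ppm (0.052).

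Leaving out each mouse gave 179 to 687 genes at 1 ppm, 12720 to 13177 at 5 ppm, 10736 to 11495 at 10 ppm, 10029 to 11029 at 20 ppm, 10469 to 11246 at 40 ppm and 11206 to 11890 at 120 ppm. It gave 0 (without 40 ppm mouse 3 or 120 ppm mouse 3 or 4) to 14 (without 120 ppm mouse 2) for 120 against 40 ppm, 1 (without 120 ppm mouse 4) to 61 (without 120 ppm mouse 2) against 10 to 40 ppm, 11827 to 12686 for the trend and 0 to 1 (without 20 or 120 ppm mouse 3) over 10 to 120 ppm. The F test gave 13821 to 14127 and the overlap 9783 to 10553. Lists gave 0 to 0 by camera at 40 and 120 ppm, 10 to 17 for 120 against 40 ppm (17 without 120 ppm mouse 1) and 10 to 19 against 10 to 40 ppm. At 1 ppm the lowest count came without 1 ppm mouse 2 and the highest without 1 ppm mouse 3.

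Signs turned with the array axis for Ckm (0.00743), Mb (0.20) and Pgam2 (0.36) at 10 ppm, Cyp2f2 (0.059), Cyp2b10 (-0.0563), Scgb1a1 (-0.013) and Mki67 (-0.56) at 40 ppm, and Scgb1a1 (-0.044), Mki67 (-0.45), Hsp90aa1 (-0.0915) and Mrc1 (-0.17) at 120 ppm. At 40 ppm Cyp2f2 turned to 0.0453 under quantile normalization, 0.16 with the quartile range and 0.0228 against 1 ppm, and ran from -0.0434 to 0.00435 leaving out a mouse. Mki67 turned there to -0.0059 with centring, -0.16 with the quartile range and -0.40 against 1 ppm, where it was called lower (adjusted p = 0.0223). Mki67 turned to -0.17 at 120 against 1 ppm, and ran at 40 ppm from -0.0052 to 0.11 leaving out a mouse. Dbp ran from -0.77 to 0.13 at 40 ppm leaving out a mouse, and turned to -0.38 against 40 ppm and -0.33 against 10 to 40 ppm with the clock score, which holds Dbp. Trim41 turned to 0.0903 with the mean of probe sets in the trend. Against 10 to 40 ppm the B cell list turned with the clock score (adjusted p = 0.981) and the fat tissue list leaving out 120 ppm mouse 3 (adjusted p = 0.549, against 0.00103 at the lowest leaving out another).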

Other observations

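Between 120 ppm and air, where 68.9% of all genes were called, genes of several stress and growth programmes differed in both directions. Of 20 cholesterol synthesis genes 10 rose and 6 fell, with Msmo1 at 2.01 ± 0.172 (SE, n = 5, in 1 of 2 probe sets) and Dhcr7 at -1.61 ± 0.189. Of 13 heat shock genes, which encode protein chaperones, 8 rose and 2 fell, with Hspa4l at 2.16 ± 0.323 and Hsp90aa1 at 1.65 ± 0.336, and of 20 genes of endoplasmic reticulum stress 11 rose and 5 fell, with Hspa5 at 1.60 ± 0.194 and Chac1 at -1.92 ± 0.183. Of 31 DNA replication genes 10 rose and 12 fell, with Mcm4 at 2.41 ± 0.162 and Mcm2, its partner in the replicative helicase, at -1.54 ± 0.162, and the mitosis genes Cenpa and Cdc20 fell by 1.27 and 1.10 on the log2 scale. Of 23 p53 targets 9 rose and 9 fell, with Mdm2 at 2.01 ± 0.119 and Phlda3 at -1.61 ± 0.127. For each list with counts the same numbers passed when adjusted over the list alone, and camera called 0 of 39 lists (5 at an unadjusted p under 0.05, 20 by fry). The arrays stood apart (first component -0.105 against 0.237), and with the array axis as a covariate Dhcr7 (-0.35, adjusted p = 0.331), Hspa4l (0.41, adjusted p = 0.61), Hspa5 (0.37, adjusted p = 0.346) and Cdc20 (-0.30, adjusted p = 0.461) lost their calls and Hsp90aa1 turned to -0.09 (adjusted p = 0.931).

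Markers of other cells also went both ways at 120 ppm against air, where 68.9% of all genes were called. Of 8 smooth muscle markers 2 rose and 5 fell, with Cnn1 at -2.06 ± 0.325 and Mylk at 0.66 ± 0.0849, and of 15 hypoxia and glycolysis genes 6 rose and 4 fell (6 and 5 when adjusted over the list alone), with Pdk1 at 1.91 ± 0.152 and Slc2a1 at -1.42 ± 0.16. Of 10 markers of interstitial macrophages and monocytes 4 rose and 4 fell, with Mrc1 at 1.71 ± 0.256 and Adgre1 at 1.04 ± 0.145. Plasma cell genes split, with the J chain gene Jchain at 2.30 ± 0.393 and Igha at -1.90 ± 0.183. Of 10 neutrophil markers 1 rose and 3 fell, with Camp at -1.12 ± 0.285. Endothelial markers rose in 6 of 15 and fell in 8, with a median of -0.33, a mean of 0.04 and a list test that pointed down (adjusted p = 0.958). With the array axis as a covariate Cnn1 (-0.22, adjusted p = 0.806), Mylk (0.22, adjusted p = 0.243), Slc2a1 (-0.53, adjusted p = 0.11), Adgre1 (0.63, adjusted p = 0.0789), Jchain (1.93, adjusted p = 0.0573) and Camp (-0.89, adjusted p = 0.259) lost their calls, and Mrc1 turned to -0.17 (adjusted p = 0.74).

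The spread of the clock among mice of 1 group followed the mouse numbers, in tests chosen after the clock genes had been seen; the named-gene rule, the lists and the comparisons with air were set before the data were examined. Same-numbered mice of different groups shared 66.7% of the spread of the clock score within groups (permutation p = 1e-04, the smallest that the permutations can give), against 14.1% for the median gene. A candidate explanation is that mice were killed in the order of their numbers, so that same-numbered mice died at like times of the morning. With mice exchanged only among those of the same number, the clock score at 120 ppm was higher than at 10 to 40 ppm (exact two-sided permutation p = 0.000977, the smallest that 1024 arrangements allow) and higher in 5 of 5 numbers, which leaves chance open, because the genes of the score were picked after their values at 120 ppm had been seen. Against 40 ppm it was higher in 5 of 5 numbers, where 32 arrangements allow no p below 0.0625. The labels give no times of death, and another order of handling that follows the numbers was not tested.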
